A study of Mus musculus with 11 samples.

How the data were processed

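RNA of mouse mitral leaflets was sequenced from 11 libraries. Per the submitters' protocol notes, total RNA was extracted with an RNeasy kit, treated with DNase and made into libraries with the SMART-Seq v4 low-input kit. The Ift88 experiment holds 3 knockout and 2 wild-type libraries and the Dzip1 experiment 3 S14R/+ and 3 wild-type libraries, grouped by the genotype in the sample labels. Each experiment has its own deposited table, and the 2 tables were analysed apart. Per the submitters' processing notes, FastQC 0.11.5, cutadapt 1.11, HTSeq, DESeq2 and DESeq were used with the mouse build GRCm38. The aligner, the annotation, the strand setting and the versions of the last 3 tools are not given in the sources used here.

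Each deposited table lists counts per gene in a column per library, whole numbers with different totals, per the file headers and the values. Beside them stand results computed by the authors: a signal per gene, the mean of the counts divided by size factors (baseMean). The log2 values in the deposited tables are fold changes between 2 groups of libraries with their standard errors, computed by the authors from the counts, per the file headers. They also give, as deposited by the authors, a score, the fold change over its standard error, and a p-value with its adjusted p-value. Which columns the authors compared is not stated in the tables and was checked by refitting every split of the libraries with DESeq2 (shrunken fold changes) and correlating the statistics across genes.

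The deposited tables list 24062 genes for Ift88 and 26667 for Dzip1, of which 6914 and 5654 had no count in any library. Total counts were 31.7 ± 8.46 M (SD, n = 3) in the Ift88 knockout, 42.6 ± 15.8 (SD, n = 2) in its wild type, 90.0 ± 3.79 (SD, n = 3) in S14R/+ and 77.6 ± 2.17 (SD, n = 3) in its wild type. The biological coefficient of variation was 87.7% in the Ift88 experiment and 7.85% in the Dzip1 experiment. Libraries were checked for copies of each other. The closest pair, Dzip1 wild-type replicate 2 and S14R/+ replicate 2, differed by a chi-squared of 11.2 per degree of freedom. Spearman correlations between libraries ranged from 0.784, between the 2 Ift88 wild-type libraries, to 0.998 in the Dzip1 experiment. By Xist and Y-linked counts, Dzip1 wild-type replicate 3 and S14R/+ replicate 2 are female and Ift88 knockout replicate 3 is male.

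Genes were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM scaling, filterByExpr at its defaults), with a Benjamini-Hochberg adjusted p threshold of 0.05. This left 14244 and 16160 tested genes. Fold changes are mutant over wild type on the log2 scale with their standard errors, and levels are TMM-scaled CPM (counts over library size in M) with the SD between libraries. Of 28 gene lists, the 27 with at least 5 tested members were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01), adjusted over the lists; the list of sex-linked genes had 2 and 4 tested members. Beside this stand camera with an estimated correlation and fry. Calls shared by the experiments were tested per direction with Fisher's exact test, and the 100 genes with the smallest p in each direction of an experiment were tested as a set in the other. The tests, the lists, the alternatives said here to be chosen in advance and the rule for named genes were fixed before the data were examined.

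By that rule the text names Ift88 and Dzip1, the genes with the largest fold changes among those past the threshold, up to 3 measured members of a list, taken from those with the smallest p, and a fixed set of cross-check genes (Cby1, Ctnnb1, Axin2, Lef1, Gli1, Ptch1, Col1a1, Col3a1, Vcan, Postn and Nfatc1). Where fewer than 4 genes passed in a direction, the choice was filled up to 4 by the smallest p. Both choices were limited to genes whose groups did not overlap and whose mean count was at least 50. The separation of the groups in these genes was therefore a condition of the choice. Predicted genes and pseudogenes were counted but not named in this part.

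The alternatives chosen in advance were DESeq2 1.42.0, limma-voom, the deposited adjusted p, RLE and upper-quartile scaling, no filter beyond 1 count and a mean count of at least 50, an adjusted p threshold of 0.1, no sex-linked genes, each library left out in turn, and for Ift88 the IR28N libraries alone and the title prefix as a covariate. After seeing the data, a correction for transcript length in each library (lowess, span 0.3), the mean of the cardiomyocyte list as a covariate, sex as a covariate and the split that the deposited Dzip1 statistics follow were added. Where a left-out library leaves 1 wild-type library, that lone sample is assumed to vary like the others. Transcript lengths came from GENCODE M21: of 28591 gene symbols 26404 had a transcript, 24247 under the same symbol and 2157 through a RefSeq synonym.

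The steps were tested on simulated data with the dispersions of each experiment. The changed genes were raised or lowered in turn. In the Ift88 design edgeR found 0% of 100 genes changed 4-fold and 30% of 100 changed 16-fold, with 0 false calls. DESeq2 found 28% and 86% of them, with 149 false calls. In the Dzip1 design edgeR found 97% of 100 genes changed 1.5-fold and 100% of 100 changed 2-fold, with 17 false calls. DESeq2 found 99% and 100% of them, with 34 false calls. The list of raised genes was called in both designs (camera adjusted p = 0.00209 and adjusted p = 1.66e-118), and 0 unchanged lists were called. The simulated genes were drawn independently of each other. The count of 0 therefore says nothing about false list calls where the genes of a list vary together.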

Results

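RNA sequencing was run on mouse mitral leaflets, the flaps that close the valve between the left atrium and the left ventricle. The first experiment held 3 libraries labelled Ift88 knockout, from mice with floxed Ift88 and an Nfatc1-driven Cre, and 2 libraries from mice with the same Cre and wild-type Ift88. Ift88 encodes a protein of intraflagellar transport, the traffic that builds cilia. The second experiment held 3 libraries heterozygous for the S14R allele of Dzip1, which encodes a zinc finger protein of the ciliary base, and 3 wild-type libraries. Total counts per library were 31.4 and 53.8 M in the Ift88 wild type and 31.4, 40.3 and 23.4 M in the knockout. They were 78.6, 79.1 and 75.1 M in the Dzip1 wild type and 86.0, 90.5 and 93.5 M in S14R/+. The age of the mice was not given in the sources used here. The labels do not say whether each library came from a separate animal, so the p-values measure only the spread between these libraries. Intervals and floors given for counts cover counting error only.

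The first comparison addressed which transcripts differ in the leaflet when Ift88 is knocked out. Collagen genes, which encode the fibres that carry the load on a leaflet, were higher as a group in the knockout libraries: the 26 measured collagens had a median log2 fold change of 1.95, and 24 of them were positive (adjusted p = 0.25 with an estimated correlation). Col1a1 stood at 363 ± 128 CPM (counts scaled to library size) (SD, n = 3) in the knockout and 43.0 ± 4.63 (SD, n = 2) in the wild type. Tnc, which encodes the matrix glycoprotein tenascin C, stood at 74.6 ± 14.2 against 5.57 ± 2.34, and Hspg2, which encodes perlecan, at 131 ± 32.5 against 11.2 ± 5.54. Lists of ribosomal protein genes and of mitochondrial oxidative phosphorylation genes were lower, with medians of -0.61 and -0.89 (adjusted p = 0.64 and adjusted p = 0.70 with an estimated correlation). The second median turned to 1.00 without wild-type replicate 1. No single gene passed the threshold in edgeR, while DESeq2 called 379 genes.

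Ift88 itself lies on chromosome 14 of GRCm38 from 57424062 to 57517936 on the forward strand. Its level was 7.54 and 19.8 CPM in the wild-type libraries and 3.00, 3.92 and 0.409 in the knockout libraries, from 198 and 1143 counts against 95, 166 and 10. All 3 knockout libraries lay below both wild-type libraries, with a log2 fold change of -2.48 ± 1.13 (SE) that did not pass the threshold (adjusted p = 0.802 in edgeR). The counts cover the whole gene and do not show which exons remained. Dzip1, on the reverse strand of the same chromosome from 118875520 to 118925460, stood at 4.39 ± 2.55 (SD, n = 3) in the knockout and 0.574 ± 0.758 (SD, n = 2) in the wild type. Its log2 fold change of 2.91 ± 1.78 (SE) did not pass the threshold.

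**Figure D1:**
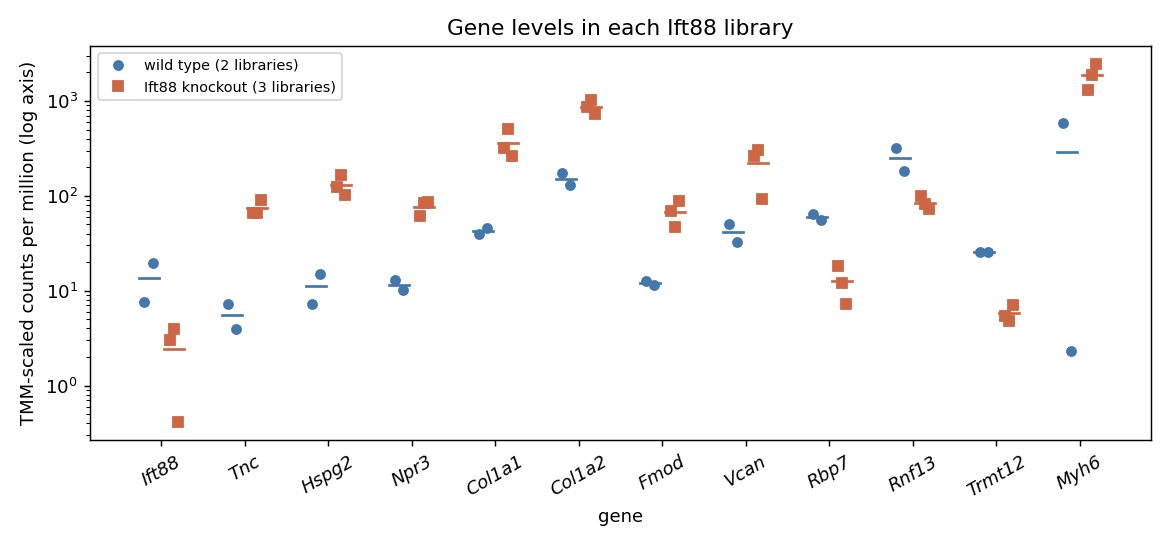
Levels of 12 genes in each Ift88 library, in TMM-scaled CPM on a log axis; circles are the 2 wild-type libraries, squares the 3 knockout libraries, and bars the group means. The squares lie above the circles for Tnc, Hspg2, Npr3, Col1a1, Col1a2, Fmod, Vcan and Myh6 and below them for Ift88, Rbp7, Rnf13 and Trmt12, while the wild-type libraries differ widely for Myh6.

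Among the collagens, camera called the list higher (adjusted p = 8.37e-15; adjusted p = 0.25 with an estimated correlation). The list's mean log2 level was 4.43 ± 0.395 (SD, n = 3) in the knockout and 2.37 ± 0.494 (SD, n = 2) in the wild type. edgeR called 0 of its members over all genes and 11 adjusted over the list alone, and DESeq2 called 9, all higher. In 16 of the 26 genes every knockout library lay above both wild-type libraries. The log2 fold changes of Col1a1 and Col1a2, the chains of type I collagen, were 3.08 ± 0.457 and 2.53 ± 0.41 (SE). Col3a1, the chain of type III collagen, had 1.53 ± 0.54. Col5a3, a chain of type V collagen, had 1 count over the wild-type libraries against 173, 344 and 194 in the knockout libraries, a ratio of 606 with a 95% counting interval of 108 to 23979. With the 3 collagens that had a group at 0 set to their bound, the list's median stayed at 1.95.

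The list of elastic fibre and matrix glycoproteins was higher with a median of 1.33 over 28 genes, 26 of them positive (adjusted p = 1.13e-12; adjusted p = 0.344 with an estimated correlation). Its median was 0.79 without wild-type replicate 1 and 2.56 without wild-type replicate 2. Tnc had a log2 fold change of 3.75 ± 0.503 (SE), Fbn2, a fibrillin of the elastic microfibril, 1.91 ± 0.38, and Mfap4, another microfibril protein, 1.34 ± 0.334. Of this list 2 genes passed when adjusted over the list alone, and DESeq2 called 4. Postn, which encodes the matricellular protein periostin, had 1.73 ± 0.608. The list of proteoglycans and hyaluronan had a median of 0.45 over 26 genes, 21 of them positive (adjusted p = 1.95e-05; adjusted p = 0.25 with an estimated correlation). Its median was 1.03 without wild-type replicate 1 and 1.51 without wild-type replicate 2. Hspg2 had 3.54 ± 0.521, Fmod, which encodes the collagen-binding fibromodulin, 2.50 ± 0.45, Bgn, which encodes biglycan, 1.84 ± 0.39, and Vcan, which encodes versican, 2.41 ± 0.618. Adjusted over the list alone, 4 genes of this list passed. The lists of glycoproteins and proteoglycans keep their direction in each of these fits.

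Cell junction and polarity genes were higher with a median of 0.75 over 30 genes, 27 of them positive (adjusted p = 1.98e-06; adjusted p = 0.25 with an estimated correlation). Tjp1, a scaffold of tight junctions, stood at 72.8 ± 4.26 CPM (SD, n = 3) against 23.3 ± 1.04 (SD, n = 2). The protocadherins Dchs1 and Fat1, which act in tissue polarity, stood at 30.9 ± 4.92 against 5.85 ± 3.81 and at 22.8 ± 4.08 against 3.00 ± 2.81. The median of the TGF-beta and BMP pathway list was 0.89 over 28 genes (adjusted p = 1.17e-05; adjusted p = 0.344 with an estimated correlation), and the call ended without wild-type replicate 1, where the median was 0.99. It was 1.37 without wild-type replicate 2. In this list Ctgf had a log2 fold change of 2.01 ± 0.44 (SE) and Tgfb2 1.54 ± 0.577. Chrdl1, which encodes a BMP antagonist, had 1 count over the wild-type libraries and 121, 860 and 38 counts in the knockout libraries.

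The next lists were called higher in the full set of libraries, but leaving out 1 library ended the call. The Wnt and beta-catenin list had a median of 0.50 over 36 genes (adjusted p = 0.00608; adjusted p = 0.344 with an estimated correlation), with 0.41 and no call without wild-type replicate 1 and 1.40 without wild-type replicate 2. Apc, a part of the complex that degrades beta-catenin, had a log2 fold change of 2.92 ± 0.598 (SE), the receptor gene Ror2 1.96 ± 0.529 and Bambi -1.15 ± 0.329. Ctnnb1, which encodes beta-catenin, had 0.46 ± 0.363, Axin2 1.90 ± 1.70, Lef1 -0.50 ± 0.733 and Cby1 -0.26 ± 0.495, and none of these genes passed the threshold. The chondrogenic and osteogenic list had a median of 1.20 over 15 genes (adjusted p = 0.0333; adjusted p = 0.344 with an estimated correlation). It was 1.09 and not called without wild-type replicate 1, 2.55 without wild-type replicate 2 and 0.70 without knockout replicate 2. Sox5 and Spp1 of this list had log2 fold changes of 2.65 ± 0.914 and 4.61 ± 1.59. Acan had no count in the wild type and 3, 50 and 79 in knockout replicates 1, 2 and 3, 132 together, at least 37.5-fold higher over the group. Against a group at 0, such bounds use a floor of 3 counts over the group. The Hedgehog list had a median of 0.77 over 16 genes (adjusted p = 0.0472; adjusted p = 0.663 with an estimated correlation). It was 0.74 and not called without wild-type replicate 1, 2.44 without wild-type replicate 2, 0.51 without knockout replicate 1, and 0.48 and not called without knockout replicate 3. Gli2 had no count in the wild type and 43, 152 and 1 in knockout replicates 1, 2 and 3, at least 55.7-fold higher over the group. Boc had a log2 fold change of 1.72 ± 0.725 and Cdon 4.95 ± 2.16, while Gli1 and Ptch1, targets of the pathway, had -0.44 ± 2.85 and 0.63 ± 1.10.

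The valve interstitial and endocardial regulators had a median of 0.52 over 29 genes (adjusted p = 0.0333; adjusted p = 0.344 with an estimated correlation). The call ended without wild-type replicate 1 (median 0.58) and without knockout replicate 3 (median 0.60), and the median was 0.93 without wild-type replicate 2. Notch1 stood at 110 ± 21.7 CPM (SD, n = 3) against 29.4 ± 19.9 (SD, n = 2) and Tbx20 at 430 ± 60.0 against 106 ± 89.9. Nfatc1, the gene whose promoter drives the Cre, stood at 303 ± 233 against 231 ± 246. Collagen processing genes had a median of 0.36 over 21 genes (adjusted p = 0.048; adjusted p = 0.344 with an estimated correlation). That call ended with another scaling (RLE, median 0.29), without wild-type replicate 1 (0.12), without knockout replicate 1 (0.20) and without knockout replicate 3 (0.45), and the median was 0.81 without wild-type replicate 2. The collagen cross-linking enzymes Loxl2 and Loxl1 had log2 fold changes of 2.40 ± 0.62 and 1.53 ± 0.402 (SE), and the procollagen peptidase Adamts2 had 2.10 ± 0.57. The smooth muscle and pericyte list had a median of 0.81 over 16 genes (adjusted p = 0.00809; adjusted p = 0.427 with an estimated correlation), with 1.81 without wild-type replicate 1 and 0.53 and no call without wild-type replicate 2. Pdgfrb had 1.64 ± 0.381, Mcam 1.22 ± 0.397 and Kcnj8 -1.32 ± 0.433.

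The libraries differed in their content of heart muscle transcripts. The mean log2 level of the cardiomyocyte list was 10.1 in wild-type replicate 1, 1.19 in wild-type replicate 2 and 9.26, 9.27 and 9.46 in the knockout libraries. Over all libraries this list was called higher with a median of 0.26 over 25 genes (adjusted p = 7.23e-05; adjusted p = 0.67 with an estimated correlation). Its direction turned with the library left out: the median was 8.59 without wild-type replicate 1, -0.73 without wild-type replicate 2, 0.40 without knockout replicate 2 and 0.0029 without knockout replicate 1. Sln stood at 368 ± 324 CPM (SD, n = 3) against 1.76 ± 1.55 (SD, n = 2), Myl7 at 4034 ± 3481 against 283 ± 386 and Myh6 at 1891 ± 575 against 293 ± 411. Mitochondrial oxidative phosphorylation genes were lower in all 28 measured members (adjusted p = 0.00265; adjusted p = 0.70 with an estimated correlation). Their median turned to 1.00 without wild-type replicate 1 and was -1.67 without wild-type replicate 2. Ndufv2, Ndufb3 and Ndufa4 had log2 fold changes of -1.08 ± 0.73, -0.84 ± 0.577 and -0.82 ± 0.595 (SE). The endothelial list was called higher with a median of 0.30 over 21 genes (adjusted p = 0.0333; adjusted p = 0.70 with an estimated correlation), but was -0.52 and called lower without wild-type replicate 1 and 2.39 without wild-type replicate 2. Without knockout replicate 2 (0.21) or knockout replicate 3 (0.47) it was not called. Npr3, which encodes the clearance receptor of natriuretic peptides, was the 1 gene of that list that passed when adjusted over the list alone, with 2.75 ± 0.407. Vwf and Emcn, markers of endothelium, had 2.41 ± 0.745 and 1.28 ± 0.412.

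Ribosomal protein genes were lower in 44 of 46 members (adjusted p = 4e-09; adjusted p = 0.64 with an estimated correlation), with a median of -0.25 without wild-type replicate 2. Rps14, Rps9 and Rps18 stood at 655 ± 105, 353 ± 43.2 and 494 ± 88.6 CPM (SD, n = 3) in the knockout and 1398 ± 523, 704 ± 316 and 963 ± 372 (SD, n = 2) in the wild type. Single genes on the lower side were chosen by the smallest p among those without overlap and with a mean count of at least 50. They were Rbp7, at 12.6 ± 5.53 against 60.4 ± 5.79, Rnf13, at 84.7 ± 14.3 against 252 ± 95, and Trmt12, at 5.78 ± 1.18 against 25.7 ± 0.00248. The fourth gene of that rule was Oprl1, which encodes the nociceptin receptor. It had 94 and 574 counts in the wild-type libraries, 668 together, and none in the knockout, at least 261-fold lower. None of the 4 passed the threshold in edgeR (adjusted p = 0.802), and DESeq2 called each of them, with adjusted p from 0.000111 to 0.0165. The corresponding genes on the higher side, Tnc, Hspg2, Npr3 and Col1a1, had adjusted p = 0.802 in edgeR and from 7.58e-09 to 2.00e-07 in DESeq2.

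Of the genes with at most 3 counts over both wild-type libraries, 7 had at least 100 counts in every knockout library, a set chosen after the values were seen. Frmpd1, Inadl and Ereg had no count in the wild type and were at least 362-fold, 222-fold and 182-fold higher. Camk1d, Col5a3, Pag1 and Prkdc had 1 or 2 counts there, and the ratios of Camk1d, Pag1 and Prkdc were 3068 (95% counting interval 550 to 121208), 289 (79.6 to 2388) and 479 (132 to 3962). The other 9 ways to choose a pair of low libraries gave 0 to 22 such genes.

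The list of intraflagellar transport and ciliary structure genes was not called (median 0.23 over 46 genes, adjusted p = 0.724). Dync2h1, the motor of retrograde transport, had a log2 fold change of 3.58 ± 1.94 (SE), and Kif3a, a motor of anterograde transport, 0.75 ± 0.441. Lists of other cell types were not called either: epicardial and mesothelial markers (median 1.78, adjusted p = 0.113), erythroid and platelet markers (-1.14, adjusted p = 0.127), melanocyte and Schwann markers (0.55, adjusted p = 0.298) and adipocyte markers (0.32, adjusted p = 0.346). The macrophage and leukocyte list had a median of -0.08 and a mean of 0.88, and camera gave it the positive direction without a call (adjusted p = 0.439). The interferon list had a median of -0.01, a mean of 0.12 and the negative direction (adjusted p = 0.306). Matrix proteases and inhibitors (0.57, adjusted p = 0.127), cell cycle genes (-0.07, adjusted p = 0.304), immediate early and stress genes (0.35, adjusted p = 0.37), MAPK and Egr feedback genes (0.40, adjusted p = 0.439) and glycolysis and hypoxia genes (-0.37, adjusted p = 0.764) were not called. Several of these lists were called in other fits. The epicardial list was called higher without knockout replicate 1 (2.06), at a mean count of at least 50 (3.08) and after the length correction (2.05), and the adipocyte list without wild-type replicate 1 (4.32). The erythroid list was called lower without wild-type replicate 1 (-0.39) or knockout replicate 2 (-1.36), cell cycle genes without wild-type replicate 2 (-0.24) or knockout replicate 1 (-0.22), and interferon genes without knockout replicate 1 (-1.01). Without wild-type replicate 2 the protease (1.16), leukocyte (1.13) and immediate early (0.97) lists were called higher, as was the leukocyte list without knockout replicate 2 (0.22). The glycolysis list was called higher without wild-type replicate 1 (1.20) and lower without wild-type replicate 2 (-0.73). Adjusted over the list alone, 0 genes passed in every list for which no count is given here. Adam19 of the protease list had 2.01 ± 0.416, and Hk2 and Hk1 of the glycolysis list had 3.85 ± 1.43 and 1.17 ± 0.461.

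Fold changes in this comparison followed transcript length. The median log2 fold change went from -0.49 in the shortest of 5 equal groups of genes through -0.23, -0.04 and 0.22 to 0.77 in the longest group, with a Spearman correlation of 0.470 across genes, which are not independent replicates. The collagens have a median transcript length of 5763 bases and the ribosomal protein genes one of 992 bases. After a correction for length in each library the collagen median was 1.21, that of the glycoproteins 0.82 and that of the junction genes 0.33. The TGF-beta and BMP median was then 0.39, the Wnt median 0.30 and the smooth muscle median 0.49. Each of these lists was still called, as was the cardiomyocyte list, with a median of 0.45 against 0.26 before. The ribosomal (-0.23), oxidative phosphorylation (-0.38), valve regulator (0.23) and Hedgehog (0.39) lists were then not called. The endothelial list was still called in the positive direction, although its median was -0.03 (camera adjusted p = 0.0281). The macrophage and leukocyte list, not called before, was then called with a median of 0.30 (camera adjusted p = 0.0422).

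**Figure D2:**
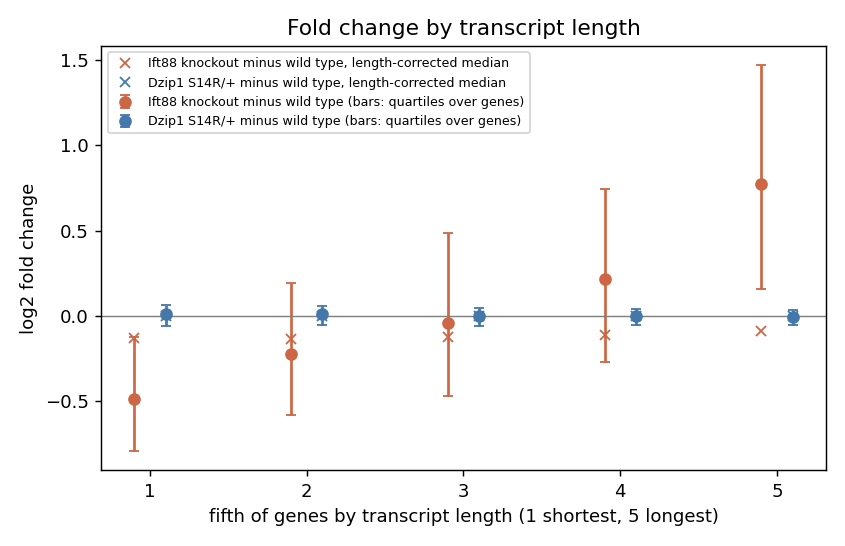
Median log2 fold change of genes in 5 groups of equal size by transcript length, for the Ift88 comparison and the Dzip1 comparison; bars span the quartiles over genes and crosses mark the medians after the length correction. The Ift88 medians go from -0.49 in the shortest genes to 0.77 in the longest, and the Dzip1 medians stay near 0.

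In edgeR 0 of 14244 tested genes passed the threshold (smallest adjusted p = 0.802). Of these, 856 had an unadjusted p under 0.05, against 712.2 by chance, 677 of them higher and 179 lower. DESeq2 called 379 genes (361 higher, 18 lower), limma-voom called 0, and the authors' deposited table called 184 (175 higher, 9 lower), all 184 among the 379. On the other 9 splits of the 5 libraries into 2 and 3, DESeq2 called 119 to 251 genes, and in simulated data of this design it made 149 false calls. The groups did not overlap for 13.5% of the genes on the higher side and 11.1% on the lower side, where chance gives 10% each. The biological coefficient of variation was 87.7%. Camera called 15 of 27 lists (13 higher, 2 lower), and with an estimated correlation or with fry's directional test 0 were called, with smallest adjusted p = 0.25 and adjusted p = 0.0613. Without wild-type replicate 1, edgeR called 187 genes, of which 4 were among the 379, and Actc1 and Myom1, genes of the heart muscle sarcomere chosen after their values were seen, were among those with the smallest p. Only the libraries whose titles start with IR28N hold both genotypes, 1 wild type and 2 knockout, and in them edgeR called 0 genes and the collagen median was 2.70; the other prefixes hold 1 library each.

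The second comparison addressed which transcripts differ in leaflets that carry the S14R allele of Dzip1. Differences were small. Erythroid and platelet genes were lower in S14R/+ with a median log2 fold change of -0.78, and macrophage and leukocyte genes and collagens were lower with medians of -0.31 and -0.21 (adjusted p = 0.222, 0.236 and 0.222 with an estimated correlation). Glycolysis, cardiomyocyte and oxidative phosphorylation genes were higher with a median of 0.10 each (adjusted p = 0.222, 0.222 and 0.236 with an estimated correlation). Csf1r, the growth factor receptor of macrophages, stood at 29.4 ± 2.17 CPM (SD, n = 3) in S14R/+ and 37.1 ± 3.36 (SD, n = 3) in the wild type. No single gene passed the threshold in edgeR or DESeq2.

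Dzip1 stood at 28.7 ± 0.721 CPM (SD, n = 3) in S14R/+ and 29.9 ± 1.98 (SD, n = 3) in the wild type, a log2 fold change of -0.06 ± 0.0587 (SE). Ift88 stood at 12.2 ± 0.213 against 12.3 ± 0.785. Counts per gene do not separate the mutated allele from the normal one.

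Of the erythroid and platelet list, 14 of 16 genes were lower (adjusted p = 1.14e-14; adjusted p = 0.222 with an estimated correlation), and 7 passed when adjusted over the list alone. The globin genes Hba-a2, Hba-a1 and Hbb-b1 stood at 92.7 ± 36.6, 46.3 ± 15.2 and 64.5 ± 30.8 CPM (SD, n = 3) against 182 ± 51.4, 91.3 ± 31.2 and 130 ± 33.5 (SD, n = 3), and their groups overlapped. The list's median was -0.47 without wild-type replicate 1. Among macrophage and leukocyte genes 18 of 19 were lower (adjusted p = 1.15e-11; adjusted p = 0.236 with an estimated correlation), and 3 passed when adjusted over the list alone. Their median was -0.15 without wild-type replicate 3. Csf1r, Fcgr3 and Emr1 had log2 fold changes of -0.34 ± 0.0756, -0.59 ± 0.164 and -0.43 ± 0.122 (SE).

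Among the collagens 22 of 26 were lower (adjusted p = 8.86e-14; adjusted p = 0.222 with an estimated correlation), and 4 passed when adjusted over the list alone. Col9a1, Col27a1 and Col9a2, collagens of cartilage-like matrix, had log2 fold changes of -0.24 ± 0.0561, -0.25 ± 0.0694 and -0.22 ± 0.0612 (SE). Col1a1 stood at 1283 ± 91.7 CPM (SD, n = 3) against 1626 ± 422 (SD, n = 3) and Col3a1 at 1855 ± 119 against 2198 ± 292, with overlapping groups. The list's median was -0.11 without wild-type replicate 3. The list of elastic fibre and matrix glycoproteins had a median of -0.08 over 28 genes, 24 of them lower (adjusted p = 2.31e-07; adjusted p = 0.222 with an estimated correlation). Fbln5, Matn4 and Mfap2 had -0.41 ± 0.14, -0.26 ± 0.0936 and -0.16 ± 0.0572. Matrix proteases and inhibitors had a median of -0.10 over 22 genes, 20 of them lower (adjusted p = 1.32e-05; adjusted p = 0.222 with an estimated correlation), with Adamts5 at -0.20 ± 0.0594, Mmp14 at -0.15 ± 0.0505 and Adam12 at -0.24 ± 0.0875. The proteoglycan list had a median of -0.05 over 25 genes (adjusted p = 0.0163; adjusted p = 0.38 with an estimated correlation), with Gpc6, Lum and Dcn at -0.25 ± 0.0865, -0.18 ± 0.0695 and -0.18 ± 0.0678. Its call ended without wild-type replicate 2 (-0.02), S14R/+ replicate 1 (-0.03) or S14R/+ replicate 3 (-0.04), and the median was -0.10 without wild-type replicate 1 and -0.09 without S14R/+ replicate 2.

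Cardiomyocyte markers were higher in 22 of 25 genes (adjusted p = 3.86e-08; adjusted p = 0.222 with an estimated correlation), with a median of 0.05 without wild-type replicate 3. Their mean log2 level was 9.54 ± 0.00496 (SD, n = 3) in S14R/+ and 9.47 ± 0.0384 (SD, n = 3) in the wild type. Myl4 stood at 2209 ± 68.8 CPM against 2008 ± 71.3, Tnni1 at 1835 ± 57.5 against 1663 ± 143 and Myl3 at 2174 ± 73.5 against 1964 ± 178. Glycolysis and hypoxia genes were higher in 20 of 24 genes (adjusted p = 1.09e-09; adjusted p = 0.222 with an estimated correlation), and in 13 of them the groups did not overlap. Pgam1, which passed when adjusted over the list alone, had 0.18 ± 0.038 (SE), Pgk1 0.15 ± 0.0512 and Pdk1 0.13 ± 0.0489. Oxidative phosphorylation genes were higher in 21 of 28 (adjusted p = 5.09e-07; adjusted p = 0.236 with an estimated correlation), with Uqcrfs1, Sdhb and Uqcrc1 at 0.13 ± 0.0495, 0.13 ± 0.0498 and 0.13 ± 0.0501. Their median was 0.15 without wild-type replicate 2 and 0.06 without wild-type replicate 3. Cell cycle genes had a median of 0.05, with 29 of 30 positive (adjusted p = 5.57e-06; adjusted p = 0.454 with an estimated correlation), and Pcna, Mcm7 and Mcm5 at 0.10 ± 0.0483, 0.07 ± 0.0386 and 0.08 ± 0.0423. Their median was 0.08 without wild-type replicate 2, 0.03 without wild-type replicate 3, and 0.03 and not called without S14R/+ replicate 3.

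With the mean of the cardiomyocyte list of each library as a covariate, the collagen median in S14R/+ was -0.05 and still called. The medians of the leukocyte (-0.06), erythroid (-0.37), glycolysis (0.05) and protease (-0.08) lists were then not called, and those of the oxidative phosphorylation and cell cycle lists turned to -0.03 each. The covariate itself separated the genotypes: it was 9.53, 9.53 and 9.54 in S14R/+ and 9.47, 9.50 and 9.43 in the wild type. This fit therefore cannot tell cardiomyocyte content from genotype, and the lost calls and turned signs decide nothing between them.

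**Figure D3:**
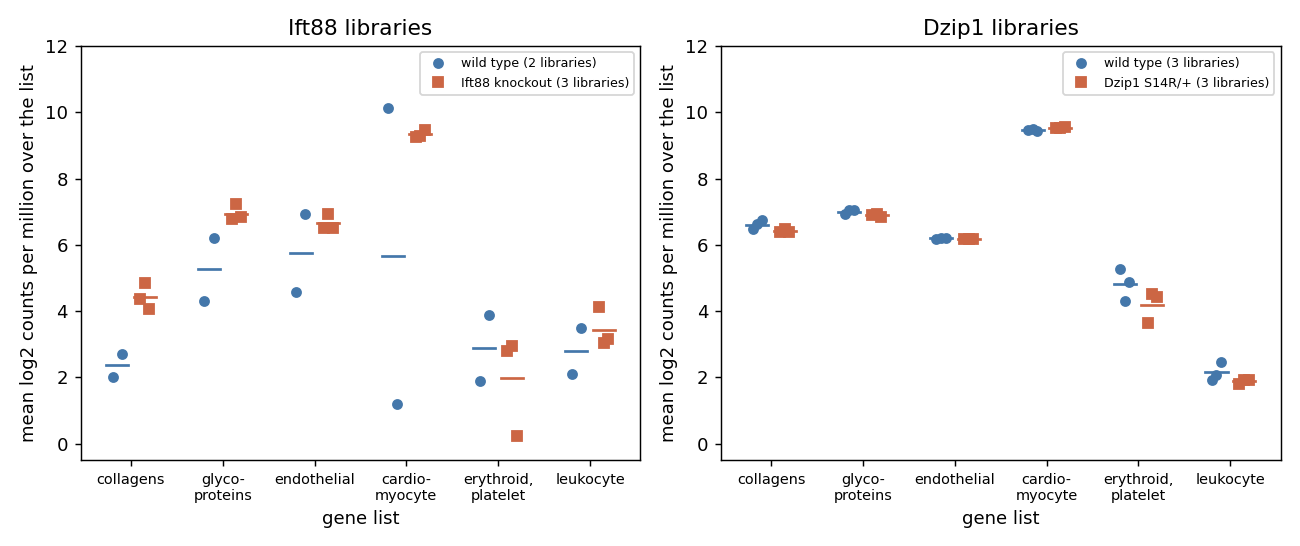
Mean log2 CPM over the members of 6 gene lists in each library, for the Ift88 libraries (left) and the Dzip1 libraries (right); circles are wild type, squares the mutant libraries, and bars the group means. The collagen level of every Ift88 knockout library lies above both wild-type libraries, 1 Ift88 wild-type library lies at 1.19 for the cardiomyocyte list, and the Dzip1 groups lie close together.

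The Hedgehog list had a median of -0.07 over 16 genes, 15 of them lower (adjusted p = 3.46e-05; adjusted p = 0.222 with an estimated correlation), and 2 passed when adjusted over the list alone. The median was -0.12 without S14R/+ replicate 2. Boc, a co-receptor of the pathway, had -0.21 ± 0.0494 (SE), Foxf1a -1.82 ± 0.494 at a mean of 13 counts, and Osr1 -0.87 ± 0.361. Its targets Gli1 and Ptch1 had -0.52 ± 0.304 and -0.06 ± 0.0722. Ribosomal protein genes had a median of -0.04 over 47 genes (adjusted p = 6.05e-05; adjusted p = 0.454 with an estimated correlation), with Rps7, Rps20 and Rpl37 at -0.11 ± 0.0397, -0.08 ± 0.036 and -0.10 ± 0.0496, and were not called without wild-type replicate 1 (-0.05). The valve regulators had a median of -0.03 over 29 genes (adjusted p = 0.0111; adjusted p = 0.222 with an estimated correlation), with the Notch targets Hey1 and Heyl at -0.23 ± 0.0554 and -0.36 ± 0.114 and Snai1 at -0.19 ± 0.0535. They were not called without wild-type replicate 1 (-0.02), wild-type replicate 2 (-0.07) or S14R/+ replicate 3 (-0.02), and the median was -0.06 without S14R/+ replicate 1. Epicardial and mesothelial genes had a median of -0.07 over 13 genes (adjusted p = 0.0289; adjusted p = 0.586 with an estimated correlation), with Msln, Wt1 and Upk1b at -0.22 ± 0.0967, -0.16 ± 0.0869 and -0.20 ± 0.111. Their median turned to 0.04 without wild-type replicate 3, was -0.03 and not called without S14R/+ replicate 1, and was -0.12 and -0.15 without wild-type replicates 1 and 2.

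The ciliary list was not called (median -0.01 over 46 genes, adjusted p = 0.587). The Wnt list had a median of -0.03 over 38 genes (adjusted p = 0.0513), with the Wnt inhibitor genes Dkk2 and Dkk1 at -0.46 ± 0.113 and -0.85 ± 0.319 (SE), Ror2 at 0.10 ± 0.0395 and Axin2 at -0.18 ± 0.0784. Ctnnb1 stood at 1068 ± 6.62 CPM (SD, n = 3) against 1062 ± 39.9 (SD, n = 3), Cby1 at 19.9 ± 1.00 against 19.8 ± 1.65 and Lef1 at 21.4 ± 0.0272 against 21.7 ± 2.52. The smooth muscle and pericyte list was not called (median -0.03, adjusted p = 0.123), although 3 of its genes passed when adjusted over the list alone. Collagen processing (-0.02, adjusted p = 0.0932), MAPK and Egr feedback (-0.04, adjusted p = 0.186), melanocyte and Schwann (-0.10, adjusted p = 0.194), interferon (-0.04, adjusted p = 0.27), chondrogenic and osteogenic (-0.03, adjusted p = 0.315), adipocyte (-0.11, adjusted p = 0.542), TGF-beta and BMP (-0.01, adjusted p = 0.587) and immediate early (-0.04, adjusted p = 0.856) genes were not called. The junction and endothelial lists had medians of -0.01 each, while camera gave both the positive direction without a call (adjusted p = 0.66 and adjusted p = 0.868). With 1 library left out, some of these lists were called: Wnt genes lower without wild-type replicate 3 (-0.04), S14R/+ replicate 1 (-0.04) or S14R/+ replicate 2 (-0.05), and collagen processing genes lower without wild-type replicate 1 (-0.05) or S14R/+ replicate 2 (-0.06). Smooth muscle genes were called lower without wild-type replicate 1 (-0.02) and interferon genes without S14R/+ replicate 2 (-0.21). Immediate early genes were called higher without wild-type replicate 1 (0.08) and lower without S14R/+ replicate 1 (-0.14). The glycolysis, chondrogenic and TGF-beta lists each had 1 gene that passed when adjusted over the list alone, and 0 passed in every list for which no count is given here.

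Single genes were chosen by the smallest p among those without overlap and with a mean count of at least 50. On the higher side they were Myo16 (log2 fold change 0.38 ± 0.0773, SE), Pgam1, Tgfbr3 (0.16 ± 0.0351) and Plekhb2 (0.15 ± 0.0371). On the lower side they were the receptor genes Pdgfrb (-0.19 ± 0.0385), Egfr (-0.44 ± 0.0975) and Csf1r and the actin-binding Synpo (-0.17 ± 0.0381). None passed the threshold (adjusted p = 0.822 in edgeR). Of 16160 tested genes edgeR called 0, and 959 had an unadjusted p under 0.05 against 808 by chance, 389 higher and 570 lower. DESeq2 and limma-voom also called 0. The groups did not overlap for 5.27% of the genes on the higher side and 5.01% on the lower side, where chance gives 5% each. The biological coefficient of variation was 7.85%. Camera called 14 of 27 lists (4 higher, 10 lower), and with an estimated correlation or with fry 0 were called, with smallest adjusted p = 0.222 and adjusted p = 0.281. Without wild-type replicate 2 edgeR called 10 genes, all lower, without wild-type replicate 1 it called Capn11 and Thbs2, and without S14R/+ replicate 2 it called Beta-s; these 3 are named after their values were seen.

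The authors' deposited table for this experiment called 14 genes, 13 with a positive and 1 with a negative value, and DESeq2 on the labelled genotypes called none of them. The deposited statistic correlated across genes with a DESeq2 refit on the labelled genotypes with a Pearson r of 0.602 in size. The same refit on the first 3 count columns against the last 3 gave 0.997 and called 14 genes, all 14 of them those of the deposited table. The first 3 columns hold S14R/+ replicates 1 and 3 and wild-type replicate 2. For the Ift88 table the refit on the labelled genotypes gave 0.998. The deposited Dzip1 values are therefore not read here as differences between genotypes.

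**Figure D4:**
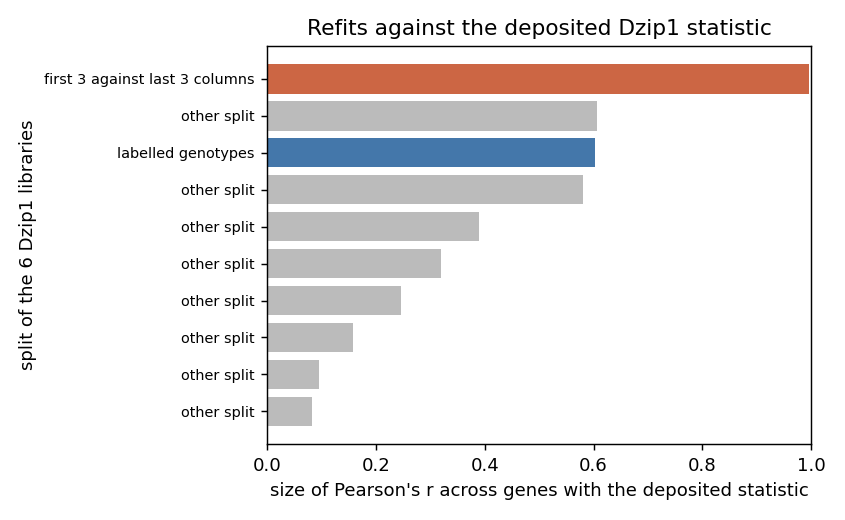
Size of Pearson's r across genes between the deposited Dzip1 statistic and a DESeq2 refit, for each of the 10 splits of the 6 libraries into 3 and 3. The split by column position reaches 0.997 and the labelled genotypes reach 0.602.

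The 2 experiments share no library. Of 12979 genes tested in both, 0 were called in both by edgeR in either direction (Fisher's exact test, two-sided, p = 1 in each direction). With 0 calls by edgeR in each experiment, and 0 by DESeq2 for Dzip1, none could be shared, so this test decides nothing. An unadjusted p under 0.05 in both was found for 67 genes, against 47.2 if the comparisons were independent, and 59 of the 67 had opposite directions. Across genes the Spearman correlation of the fold changes was -0.14. Fold changes also correlated with transcript length in opposite directions, at 0.470 for Ift88 and -0.080 for Dzip1 (Spearman). The part of this trend in the opposite directions between the experiments was not tested. The 100 genes with the smallest p on the higher side of the Ift88 comparison were lower as a set in S14R/+, with a median log2 fold change of -0.02 and 33 of 100 positive (camera adjusted p = 6.23e-04; adjusted p = 0.0476 with an estimated correlation). The 100 genes on the lower side of the Dzip1 comparison were higher as a set in the Ift88 knockout, with a median of 0.75 (adjusted p = 1.07e-05; adjusted p = 0.401 with an estimated correlation). The sets of 100 from the other 2 directions were not called (adjusted p = 0.753 each). Of genes with a positive fold change in the Ift88 knockout, Tnc and Postn had negative values in S14R/+, -0.11 ± 0.0471 and -0.08 ± 0.0568 (log2, SE). Hspg2 and Vcan had positive values there too, 0.10 ± 0.0701 and 0.08 ± 0.0736. Pdgfrb, Synpo and Egfr, lower in S14R/+ without passing the threshold, had 1.64 ± 0.381, 2.14 ± 0.503 and 1.91 ± 1.30 in the Ift88 knockout.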

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

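The length correction, the cardiomyocyte and sex covariates and the split by column position were chosen only after the results were seen; the other alternatives were planned. In the Ift88 comparison the edgeR count of 0 genes (856 at an unadjusted p under 0.05; limma-voom 0) became 379 with DESeq2 and 184 in the deposited table, and 0 to 187 with 1 library left out. The 15 called lists became 0 with an estimated correlation, 0 with fry's directional test and 5 with its mixed test, and the cause was not tested. With the title prefix as a covariate, the genotype effect came only from the IR28N libraries, 1 wild type and 2 knockout. The other prefixes hold 1 library each and add nothing to that effect. This fit is therefore no separate check beside the IR28N libraries alone. In the Dzip1 comparison the edgeR count of 0 (959 at an unadjusted p under 0.05; DESeq2 and limma-voom 0) became 14 in the deposited table, which follows another split, and 0 to 10 with 1 library left out. The 14 called lists became 0 with an estimated correlation, 0 and 0 with fry's directional and mixed tests, and 8 with the cardiomyocyte covariate; the cause was not tested. Of those 8, 1 is the sex-linked list, which had 5 tested members only in some fits, and 5 of the 14 kept their call and direction. Directions reversed for these Ift88 lists, with the range over libraries left out: oxidative phosphorylation (-1.67 to 1.00), endothelial (-0.52 to 2.39), glycolysis (-0.73 to 1.20) and cardiomyocyte (-0.73 to 8.59, and -0.74 in the IR28N libraries alone and -0.73 with the prefix as a covariate). Ift88 wild-type replicates 1 and 2 set the ends of these ranges, and their cardiomyocyte levels differ (10.1 against 1.19). Lists not called with all libraries also changed the sign of their median: adipocyte (-0.64 to 4.32), epicardial (-0.51 to 3.23), erythroid (-1.46 to 0.77), interferon (-1.01 to 0.35), leukocyte (-0.33 to 1.13), cell cycle (-0.24 to 0.39) and protease (-0.039 to 1.16). In Dzip1 the immediate early (-0.14 to 0.078) and epicardial (-0.15 to 0.038) lists reversed, and with the cardiomyocyte covariate the oxidative phosphorylation (-0.025), cell cycle (-0.033), ribosomal (0.015), epicardial (0.17) and junction (-0.061) lists did; the cause was not tested. The Ift88 collagen list was called higher in each fit with 1 library left out (median 1.57 to 2.47), and the Dzip1 collagen list lower (-0.29 to -0.11). Of the other values under alternatives chosen in advance, 1554 for Ift88 and 1514 for Dzip1 kept their direction and side of the threshold, 51 and 37 fell short of it, 58 and 8 came to pass it, and 50 and 29 changed direction without a call. Scaling by RLE or upper quartile shifted the median of all genes by less than 0.1. Alternatives for normalised values were not run, since the tables hold counts. In simulated data of the Ift88 design edgeR found 0% of genes raised or lowered 4-fold, so changes of that size or smaller there are not excluded.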

Other observations

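The tests of the deposited Dzip1 statistic and the counts of Dzip1 genes over other splits were chosen only after the result was seen, as were the genes in the next paragraph.

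Genes of the heart chambers and of the heart's outer lining varied between the Ift88 libraries. Myl2 stood at 8650 and 9.24 CPM in wild-type replicates 1 and 2 and at 4498, 722 and 512 in knockout replicates 1, 2 and 3, and Myh7 at 1635 and 5.08 against 4006, 688 and 232. Sln stood at 2.84 and 0.663 against 0, 612 and 489, and Myl7 at 554 and 10.2 against 149, 5072 and 6859. Upk3b was listed at 0 in both wild-type libraries and in knockout replicate 1 and stood at 64.6 and 2.41 in knockout replicates 2 and 3. Among the Dzip1 libraries the ribosomal transcript Rn45s took 0.0800, 0.0803 and 0.0635% of the counts in wild-type replicates 1 and 3 and S14R/+ replicate 1, and 0.240, 0.155 and 0.199% in wild-type replicate 2 and S14R/+ replicates 2 and 3. The former 3 against the latter 3 is the split of the 6 libraries for which DESeq2 called 155 genes; in simulated data of this design it made 34 false calls.

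The deposited Dzip1 statistics may come from a test of the first 3 count columns against the last 3. A refit on that split correlated with them at 0.997 in size, the highest of the 10 splits, and the refit on the labelled genotypes reached 0.602, which argues against a test on the genotypes as labelled. Whether instead the genotype labels of a library in each group were exchanged cannot be told apart: DESeq2 called 19 genes on that split, 0 on the labelled split and up to 155 on the others, and the size of the genotype's effect is not known. The chi-squared per degree of freedom of wild-type replicate 2 was 17.0, 11.2 and 12.5 against S14R/+ replicates 1, 2 and 3. Against wild-type replicates 1 and 3 it was 29.9 and 31.2. For S14R/+ replicate 2 it was 15.9 and 13.6 against S14R/+ replicates 1 and 3. Against those wild-type libraries it was 26.6 and 27.8. Both libraries thus lay nearer to the other S14R/+ libraries, which does not settle the labels. No biological explanation was tested.

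The higher matrix lists in the Ift88 knockout may reflect the genotype, transcript length or the make-up of the samples. The length trend argues against being the whole cause, since the collagen median was 1.21 after the length correction against 1.95 before, with the list still called, although part of the difference went with it. Cardiomyocyte content was entered through the list's mean as a covariate, and the collagen median was then 2.50. That mean was 1.19 in wild-type replicate 2 and from 9.26 to 10.1 in the other libraries. The covariate therefore mostly sets that library apart and leaves mainly wild-type replicate 1 to compare with the knockout. So the fit cannot tell cardiomyocyte content from other differences of wild-type replicate 2. In that fit 13 of the 15 called lists kept their call and direction. The smooth muscle and pericyte list and the cardiomyocyte list itself were not called. Other medians moved as well, to 2.12 for endothelial, 2.17 for Hedgehog, 1.33 for Wnt and -0.31 for ribosomal protein genes. Of the 10 splits of the 5 libraries into 2 and 3, 1 called as many lists (15 in the real split, 14 in the highest other), and 10 splits cannot give a share under 0.05. Cardiomyocyte content, other differences in tissue make-up or dissection, and the batch behind the title prefixes stay open, as does the genotype.

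The Dzip1 list differences could come from a higher share of cardiomyocytes in the S14R/+ libraries or from a single wild-type library. A higher share would lower collagens and endothelial markers alike; their contrast was -0.17 with a standard error of 0.071, a ratio of 2.44 in size, which stays inside the bound set in advance, so this cannot be told apart. Without wild-type replicate 3 the collagen median was -0.11 against -0.21, right at the bound set in advance and still called, so that library carries much of the difference. Of the 10 splits of the 6 libraries 1 called as many lists (14 in the real split, 12 in the highest other), and 10 splits cannot give a share under 0.05. For genes, all 10 splits called as many in edgeR (0, highest other 2; 959 genes at an unadjusted p under 0.05, limma-voom 0) and 10 in DESeq2 (0, highest other 155), which a real count of 0 makes certain, so these counts say nothing about chance; the split with 155 genes points to a structure of the samples whose cause was not tested.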
